A study of Mus musculus with 6 samples.

How the data were processed

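RNA from mouse jejunal organoids was sequenced in 6 libraries, 3 from organoids treated with the vehicle DMSO and 3 from organoids treated with 4-hydroxytamoxifen (4OHT). Per the labels' protocols, the organoids carried a tamoxifen-inducible Cre recombinase under the villin promoter and floxed Hnf4a alleles, received 0.5 µM 4OHT or vehicle for 24 hours, were split, and were grown with 200 ng/mL recombinant Wnt3A until harvest at day 2. RNA was purified on columns, and 250 ng went into poly(A)-selected libraries made with a directional kit, per the labels' protocols. STAR 2.4.0f1 and bcl2fastq 1.8.4 were named, and GRCm38 was the genome build, per the submitters' processing notes. The program that counted reads per gene and its strand setting were not stated in the sources used here, so reads shared between overlapping or antisense genes, or between near-identical copies such as the alpha-defensins, could have been split in an unknown way.

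The authors deposited one table of 18448 genes with raw counts per gene for each of the 6 libraries, per the file headers. Every gene in it had at least 10 counts in total over the 6 libraries, so genes below that level were not available. A second set of columns held a normalised score per gene and library, which from the values was the raw count divided by a nearly constant factor per library and rounded to a whole number by the authors. The factors recovered from those columns ran from 0.863 to 1.117, beside 0.867 to 1.122 for size factors computed here with DESeq2. Dividing by the recovered factors gave values within 1 unit of the deposited ones for 91.74% to 100% of genes per library. The authors also deposited a log2 fold change of 4OHT against DMSO and a mean log2 level per gene, per the file headers. Raw and adjusted p-values from DESeq and from edgeR were deposited as well, per the file headers, with no versions or models stated. The raw counts were used for every test here, and the deposited fold changes and p-values were only set beside the results.

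Of the 18448 gene identifiers, 18358 were found in GENCODE mouse release 21, which gave coordinates on GRCm38, transcript lengths and GC content, and 8 gene symbols occurred more than once. Total counts per library were 35638347, 36102703 and 31537100 for DMSO replicates 1, 2 and 3 and 34912396, 35315255 and 40276242 for 4OHT replicates 1, 2 and 3. The libraries differed by more than counting error: the chi-square statistic per degree of freedom between pairs of libraries ran from 7.86 to 98.2.

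Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14544 genes and removed 3904, and the kept genes held at least 99.95% of the counts of each library. Library sizes were scaled by the trimmed mean of M-values (TMM), and 4OHT was compared with DMSO by the quasi-likelihood F test with no other term in the model. p-values were two-sided and adjusted over the tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Levels are given as CPM (counts scaled to the TMM-adjusted library size) with the mean and standard deviation (SD) of 3 libraries, and log2 fold changes (4OHT over DMSO) with their standard error (SE). Unless another tool is named, every adjusted p of a gene is from this test.

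Replicates 1, 2 and 3 occur in both groups. The labels do not say that a number marks a shared culture or day. Deviations from the group means correlated at 0.30, 0.33 and 0.43 across genes between libraries with the same number, and at -0.37 to 0.07 between libraries with different numbers. Deviations from a group mean cancel out within the group, so positive values for the same number force lower ones for different numbers. The lower values are thus no separate evidence. The numbers were taken to pair the libraries from the positive values, seen in these same data. Values from a fit with the replicate number as a block are given wherever they changed a call or moved a count by more than 1.5 times. The labels do not say that the replicates came from separate organoid lines or animals, so p-values measure the spread between these libraries, which may be technical.

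The comparison, its test, 32 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes of 3 kinds were named: Hnf4a, Hnf4g and Wnt3 in any case; the 10 largest rises and 10 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups, leaving out predicted genes (62 genes were eligible among the rises and 22 among the falls); and up to 4 tested members with the smallest p-values from each list. Genes outside this rule are said to have been chosen after their values were seen. The lists covered Paneth cell alpha-defensins, other Paneth cell markers, Wnt ligands, Paneth-derived niche signals, Wnt/beta-catenin targets, stem cell markers, goblet, enteroendocrine and tuft cell markers, secretory lineage regulators, the Notch pathway, enterocyte brush border and nutrient transport, lipid absorption, fatty acid oxidation, xenobiotic metabolism, intestinal transcription factors, bile acid and ileal genes, proliferation, fetal-like and regenerative epithelium, cholesterol synthesis, the p53 response, the interferon response, antimicrobial and inflammatory genes, the unfolded protein response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, gastric epithelium, immediate early genes, mesenchymal, immune and endothelial cell markers, and reference genes.

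Lists with at least 3 tested members (30 lists) were tested as sets with camera in limma 3.58.1 on log2 CPM (prior count 2), with its preset inter-gene correlation of 0.01, two-sided, and adjusted over the 30 lists. The same test with a correlation estimated within each list, and fry, were alternatives. With an estimated correlation, 0 of the 30 lists passed (adjusted p from 0.746 to 0.982), and 2 had an unadjusted p under 0.05; adjusted p-values from that version are printed beside each list that passed with the preset value. With the preset value, 8 of the 10 splits of the libraries into 3 and 3, the real one included, moved at least as many lists as the real one. A list said below to rise or fall is one that passed the preset test, and such calls were not specific to the real split. For each list the number of called members is given over all tested genes and adjusted over the list alone.

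Each fit was tested on its own simulated counts for 14544 genes, with 100 genes changed 2-fold and 100 changed 4-fold. The counts were made from the real means and library sizes and the dispersions of that fit. Those for the blocked fit also held the observed effects of replicate number. The fit without the block recovered 62% and 92% of the genes changed 2-fold and 4-fold, with 8 false among 162 calls. The fit with the block recovered 76% and 97%, with 19 false among 192 calls. The fits are thus not compared on like counts, and the fit without the block was not tested on paired counts. In this simulation the blocked fit thus made more false calls than an adjusted p under 0.05 is meant to allow. Calls made only with the block are less certain for that reason. The 1 list changed in the simulated data was recovered and no other list was called in either fit. The counts of each gene were simulated independently, so this cannot show how often lists of correlated genes are called falsely.

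Alternatives were DESeq2 1.42.0, limma-voom, DESeq2-style size factors or library totals alone in place of TMM, no filter, a filter of at least 10 CPM in 3 libraries, an adjusted p under 0.01, an absolute log2 fold change of at least 1, the replicate block, and each library left out in turn. Alternatives planned for normalised values were not run because raw counts were available. Alternatives added later left out replicate 3 of both groups, with and without the block, or combined the block with DESeq2 or with an estimated correlation. The fits without replicate 3 of both groups had few residual degrees of freedom, most so with the block, so their calls are less certain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.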

Results

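Gene expression was measured by poly(A) RNA sequencing in mouse jejunal organoids, which are epithelial cultures of the small intestine. The organoids carried floxed Hnf4a alleles and a villin-driven, tamoxifen-inducible Cre recombinase. Treatment with 4OHT, the active form of tamoxifen, was compared with DMSO, with 3 libraries in each group, and all 6 had received recombinant Wnt3A. Library totals ran from 31537100 to 40276242 counts, and 14544 genes were tested. The 10 most abundant genes held 4.64% to 5.2% of the counts of a library, and mitochondrially encoded transcripts held 1.72% to 2.32%.

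DMSO replicate 3 stood apart from the other libraries of its group, and 4OHT replicate 3 did so less clearly. The chi-square statistic per degree of freedom of DMSO replicate 3 was 64.2 against DMSO replicate 1 and 58.5 against DMSO replicate 2. Between DMSO replicates 1 and 2 it was 7.86. For 4OHT replicate 3 it was 17 against 4OHT replicate 1 and 31.4 against 4OHT replicate 2, beside 15.6 between 4OHT replicates 1 and 2. On the principal component plot the first component, with 48.7% of the variance, placed the DMSO libraries at -3.03, -5.88 and -48 and the 4OHT libraries at 23.2, 23.6 and 10.1. The second, with 24.2%, placed replicate 3 of both groups (-11.8 and -26.2) below replicates 1 and 2 of the same group (22.1 and 20.7 in DMSO, -3.62 and -1.14 in 4OHT). Replicate 3 was compared per gene with the mean log2 CPM of replicates 1 and 2 of the same group. Later counts of genes higher or lower in replicate 3 than in replicates 1 and 2 refer to that mean. Both replicate 3 libraries were higher in enterocyte, xenobiotic metabolism and goblet cell genes and lower in stem cell, Wnt target and proliferation genes. Paneth cell genes went both ways. Medians for DMSO replicate 3 and 4OHT replicate 3, in log2 units, were 0.98 and 0.72 for xenobiotic metabolism, 0.83 and 0.51 for enterocyte genes, and 1 and 0.52 for goblet cell markers. They were -0.67 and -0.64 for Wnt target genes and 0 and 0 for all tested genes.

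**Figure D1:**
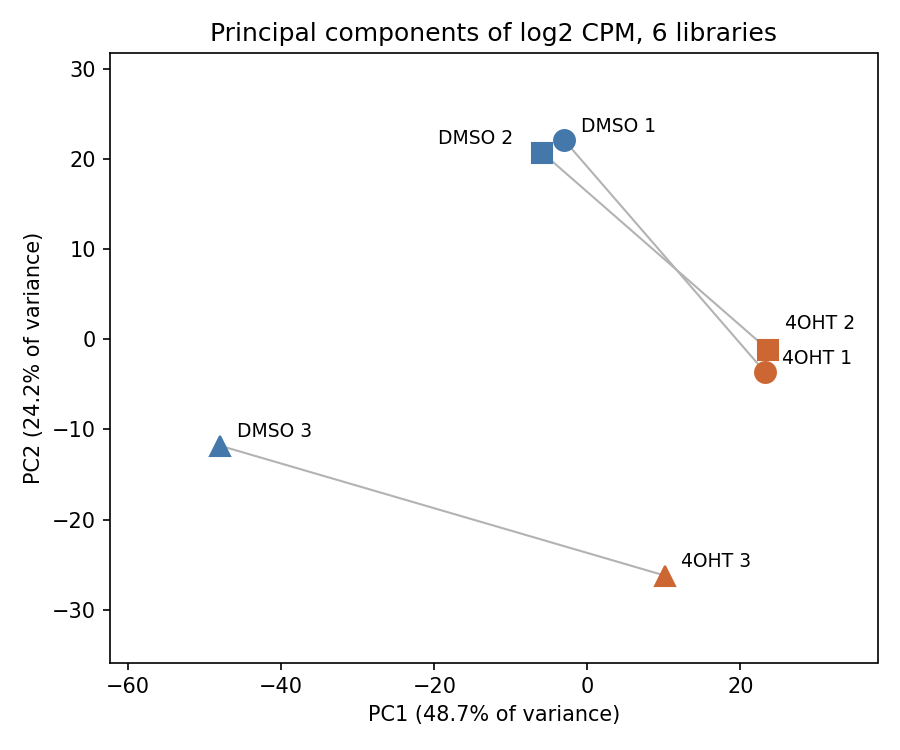
First and second principal components of log2 CPM (arbitrary units), 1 point per library, coloured by treatment and shaped by replicate number. The 4OHT libraries lie to the right of the DMSO libraries on the first component, and replicate 3 of each group lies below the other libraries of that group on the second.

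Hnf4a, the nuclear receptor gene targeted in this design, was lower in every 4OHT library than in any DMSO library. Its level was 839.8, 846.2 and 1021 CPM in DMSO replicates 1 to 3 and 435.9, 423.7 and 481.7 CPM in the 4OHT replicates. The means were 902 ± 103 and 447 ± 30.6 CPM (SD, n = 3), a 2.02-fold lower level after 4OHT (log2 fold change -1.01, SE 0.10, edgeR adjusted p = 0.0124). The gene (ENSMUSG00000017950) lies on chromosome 2 from 163506808 to 163572910 in GRCm38. The labels used here did not give the deleted exons, so counts over the whole gene do not measure the share of recombined alleles. The call was lost without DMSO replicate 1 (adjusted p = 0.0572) or 2 (0.0606) and without 4OHT replicate 1 (0.0951), 2 (0.0629) or 3 (0.0621), and was kept without DMSO replicate 3 (0.00543) and with the replicate block (0.00308). In the fits that lost the call, the log2 fold change of Hnf4a ran from -1.07 to -0.98.

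Hnf4g, the paralogue of Hnf4a in the intestine, showed no difference larger than the spread between replicates. Its gene (ENSMUSG00000017688) lies on chromosome 3 from 3508030 to 3658052. The level was 135 ± 68.5 CPM in DMSO and 123 ± 39.1 CPM after 4OHT (log2 fold change -0.13, SE 0.363, adjusted p = 0.90). Replicate 3 was highest in both groups, at 214 CPM in DMSO and 167 CPM after 4OHT. The difference changed sign to 0.36 without DMSO replicate 3 (adjusted p = 0.503) and to 0.03 without 4OHT replicate 2 (0.984), and ran down to -0.42 without 4OHT replicate 3 (0.698).

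The series title names Wnt3, a Wnt ligand gene, and Paneth cell fate, and the comparison asks how both respond to loss of Hnf4a when Wnt3A is supplied. Wnt3 (ENSMUSG00000000125, chromosome 11 from 103774150 to 103817957) measured 15.5, 16.1 and 11.2 CPM in DMSO and 10.2, 9.19 and 7.13 CPM after 4OHT. The means were 14.3 ± 2.65 and 8.85 ± 1.58 CPM (SD, n = 3), with a log2 fold change of -0.69 (SE 0.185) and a lower level after 4OHT in all 3 pairs. This missed the threshold without the replicate block (adjusted p = 0.145), and with the replicate block Wnt3 fell (adjusted p = 0.0168). DESeq2 also placed it past the threshold (adjusted p = 0.0125), as did the fit without DMSO replicate 3 (log2 fold change -0.85, adjusted p = 0.0419). Over the other alternatives its adjusted p ran from 0.141 to 0.317.

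Across all genes, 132 changed after 4OHT, 102 higher and 30 lower. With the replicate block 1017 genes changed, 580 higher and 437 lower, and these included all 132. The higher genes included Tff1, Ly6g, Ivl and Krt4, and the lower genes included Cps1, Ckb, Acta1 and Agmat. Of the 132 genes, 68 differed by at least 2-fold, 54 higher and 14 lower. The groups did not overlap for any of the 132, nor for 3285 of the tested genes (22.6%, where chance gives 10% for libraries that are not paired). At an unadjusted p under 0.05, 1258 genes were higher and 923 lower (1933 and 1750 with the block).

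Tff1, a trefoil peptide of gastric mucus, had the largest rise among the named genes, from 9.8 ± 1.21 to 128 ± 52.7 CPM (log2 fold change 3.71, adjusted p = 0.0093). Ly6g, of the Ly6 family of surface proteins, rose from 1.77 to 23.0 CPM (3.69, adjusted p = 0.00454); members of that family have near-identical copies between which reads could be shared. Ivl, which encodes the cornified envelope protein involucrin, rose from 1.71 to 15.4 CPM (3.16, adjusted p = 0.0362). Krt4, a keratin of stratified epithelia, rose from 63.5 ± 16.7 to 236 ± 38.7 CPM (1.90, adjusted p = 0.0205). The other 6 of the 10 largest rises were Mal (2.53), Fut2 (2.10), Psapl1 (1.96), Fer1l4 (1.83), Cysrt1 (1.62) and Aldh3b2 (1.62), with adjusted p between 0.0101 and 0.0459.

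Cps1, the first enzyme of the urea cycle, fell from 1339 ± 144 to 463 ± 98.3 CPM (log2 fold change -1.53, SE 0.163, adjusted p = 0.0159). Ckb, a creatine kinase, fell from 208 ± 4.32 to 96.8 ± 7.15 CPM (-1.10, SE 0.067, adjusted p = 0.00291). Acta1, an alpha-actin gene, fell from 32.7 ± 6.23 to 8.93 ± 0.539 CPM (-1.87, adjusted p = 0.00816). Agmat, which encodes agmatinase, fell from 33.3 to 14.4 CPM (-1.21, adjusted p = 0.0093). Myb, a transcription factor of proliferating progenitors, fell from 103 to 62.4 CPM (-0.73, adjusted p = 0.0107). The other genes among the 10 largest falls were Msi1 (-1.26), Tstd1 (-1.18), Hnf4a (-1.01), Slc16a12 (-0.93) and Lyz1 (-0.78).

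The calls depended on which library was left out. Leaving out 1 library gave 6 calls without DMSO replicate 1, 4 without DMSO replicate 2, 340 without DMSO replicate 3, 9 without 4OHT replicate 1, 20 without 4OHT replicate 2 and 12 without 4OHT replicate 3. Of the 10 largest rises, 9, 10, 0, 9, 5 and 8 missed the threshold without these libraries in the same order, with adjusted p between 0.0521 and 0.182. Of the 10 largest falls, 8, 9, 0, 8, 7 and 8 missed it, with adjusted p between 0.0509 and 0.187. Ckb kept its call in all of these fits.

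**Figure D2:**
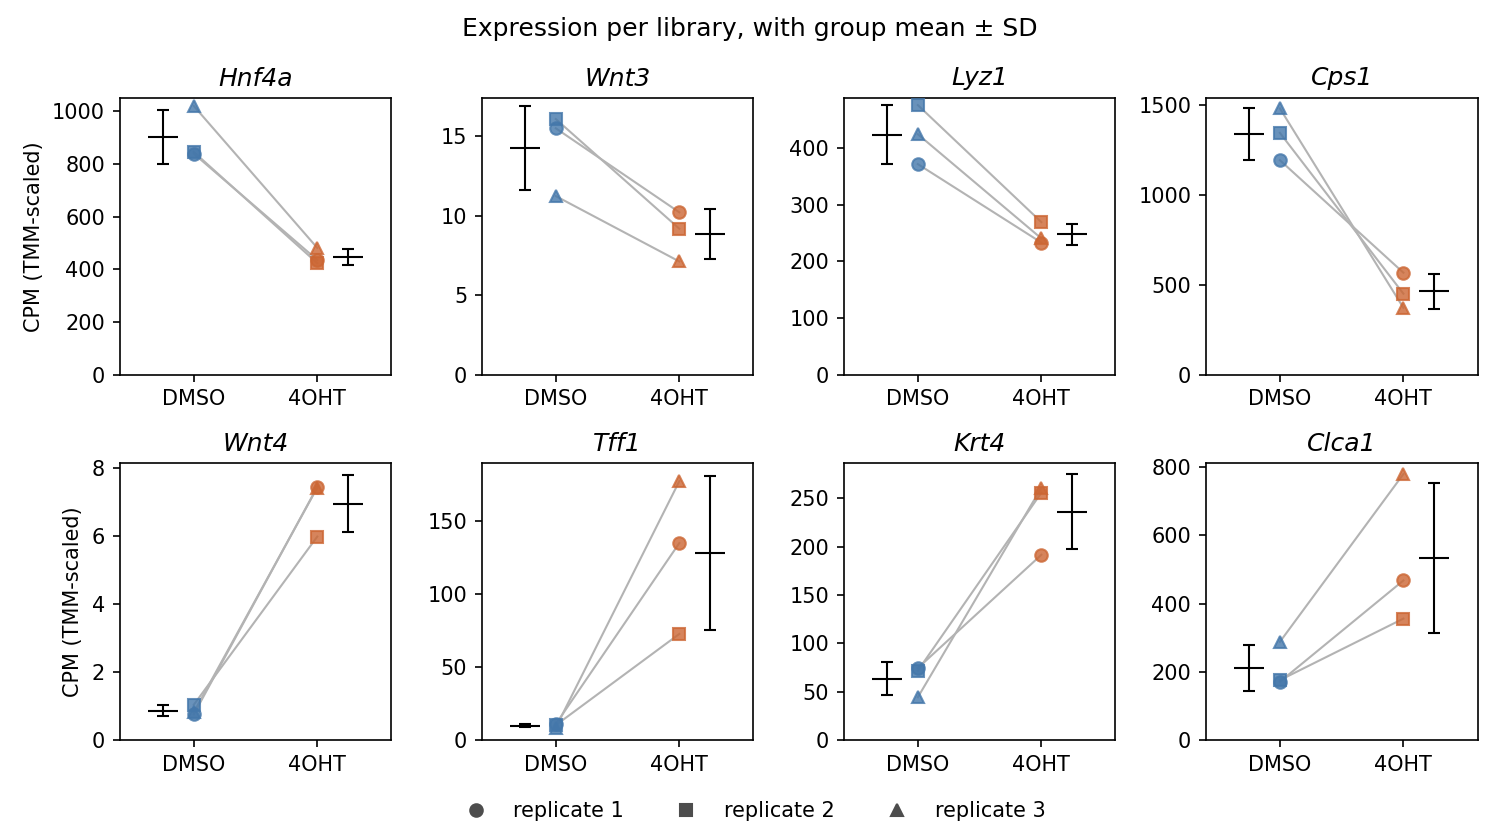
CPM of 8 genes in each library (vertical axes from 0, 1 panel per gene), with grey lines joining libraries of the same replicate number and black bars for the mean ± SD of 3 libraries. Hnf4a, Wnt3, Lyz1 and Cps1 lie lower, and Wnt4, Tff1, Krt4 and Clca1 higher, in the 4OHT library of every pair.

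Among Paneth cell genes the lysozyme gene Lyz1 fell and the alpha-defensins did not pass the test. Lyz1 fell from 424 ± 52.1 to 248 ± 19.1 CPM (SD, n = 3), a 1.71-fold lower level after 4OHT (log2 fold change -0.78, SE 0.105, adjusted p = 0.0318). Nupr1, a stress-response gene in the same list, rose from 12.7 ± 0.541 to 29.7 ± 3.96 CPM (1.22, adjusted p = 0.00944). Of 15 tested Paneth markers other than defensins, 1 rose, 1 fell and 13 did not pass, and the same 2 passed when adjusted over the list alone (1 higher and 4 lower with the block). In the fit with the replicate block Fgfrl1 (-0.40, adjusted p = 0.0446) and Pnliprp2 (-0.36, adjusted p = 0.0404, a gene chosen after its values were seen) also fell. Copz2, near the detection limit, was at 0.368 and 0.636 CPM (adjusted p = 0.335). As a set these 15 genes did not move (camera adjusted p = 0.951, median 0.05). The median and the test pointed up without the block, and the test pointed down with it (adjusted p = 0.865) and without DMSO replicate 1 (median -0.03, 0.655) or 4OHT replicate 2 (-0.02, 0.92). The median was also below 0 without DMSO replicate 3 (-0.05) or 4OHT replicate 1 (-0.03), where the test pointed up, and it was 0.02 without DMSO replicate 2.

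Of 14 tested alpha-defensins, 0 were called by edgeR, 0 by DESeq2 and 0 by limma-voom, 0 when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05. Defa24 was at 513 ± 84.6 CPM in DMSO and 462 ± 41 CPM after 4OHT (log2 fold change -0.15, adjusted p = 0.64). Gm15308 (-0.55, adjusted p = 0.299), AY761184 (-0.24, 0.649) and Defa3 (-0.24, 0.657) also missed the threshold. The camera test gave an adjusted p of 0.0867 (median -0.12), which passed without DMSO replicate 1 (0.0152) and without 4OHT replicate 1 (0.0193), while the median was -0.03 without DMSO replicate 3 and -0.08 without 4OHT replicate 3. Alpha-defensins are near-identical copies, so the split of reads among them is uncertain. Of the calls above, Lyz1 was lost without DMSO replicate 1 (adjusted p = 0.0572) or 2 (0.107) and without 4OHT replicate 1 (0.155), 2 (0.0774) or 3 (0.13), and Nupr1 without DMSO replicate 1 (0.0576) or 2 (0.0606) or 4OHT replicate 3 (0.0621).

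Wnt4 and Wnt7b, which encode 2 further Wnt ligands, rose after 4OHT. Wnt4 went from 0.866 ± 0.149 to 6.95 ± 0.838 CPM (SD, n = 3, log2 fold change 3.00, SE 0.185, adjusted p = 0.00291) and Wnt7b from 2.21 ± 0.926 to 8.49 ± 0.99 CPM (1.93, SE 0.301, adjusted p = 0.0448). Of 8 tested Wnt ligand genes 2 rose and 6 did not pass, and with the replicate block Wnt3 and Wnt9b (-1.18, adjusted p = 0.0379) also fell. When adjusted over the list alone 3 were higher and 2 lower. Relative to replicates 1 and 2 the medians of the list were -0.51 in DMSO replicate 3 and -0.26 in 4OHT replicate 3. The camera test gave an adjusted p of 0.0867 (median 0.78), which passed without DMSO replicate 2 (0.0177, where the median was 0.42) and without 4OHT replicate 3 (0.0363, median 0.81). The median was 0.51 without DMSO replicate 3 and 0.41 without 4OHT replicate 2. Wnt4 kept its call in every alternative that tested it (it was below the filter at 10 CPM), whereas Wnt7b lost it without DMSO replicate 1 (adjusted p = 0.111) or 2 (0.107) and without 4OHT replicate 1 (0.191), 2 (0.131) or 3 (0.126).

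Of 7 tested niche signals that Paneth cells are known to provide, 0 were called by edgeR and 0 by limma-voom, while DESeq2 called 1 higher and 2 lower, and 1 was higher and 3 lower at an unadjusted p under 0.05. When the replicate block was included, Tgfa rose from 47.8 to 62.5 CPM (0.38, adjusted p = 0.03) and Wnt3 and Wnt9b fell. The Notch ligand gene Dll4 was at 16.5 and 13.5 CPM (-0.29, adjusted p = 0.15). When adjusted over the list alone 1 was higher and 3 lower. The list did not move as a set (camera adjusted p = 0.278, median -0.26), and the median was -0.02 without DMSO replicate 3.

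Targets of Wnt/beta-catenin signalling did not differ as a group with Wnt3A in the medium. Of 16 tested targets edgeR, DESeq2 and limma-voom called 0, 1 was higher at an unadjusted p under 0.05 (2 higher and 3 lower with the block), and 0 passed when adjusted over the list alone (1 higher and 2 lower with the block). Under the replicate block Axin2, a feedback inhibitor of the pathway, fell from 157 ± 35.7 to 124 ± 35.7 CPM (-0.35, adjusted p = 0.0265). Ccnd1 was at 526 and 672 CPM (0.35, adjusted p = 0.324), Znrf3 at 29.1 and 26.3 CPM (0.652) and Ephb3 at 85.2 and 97.0 CPM (0.677). The list test gave a camera adjusted p of 0.89 (median -0.03), which passed without DMSO replicate 3 (0.0465, median -0.23). The median was -0.13 without 4OHT replicate 1 and -0.15 without 4OHT replicate 2, and the test pointed up without DMSO replicate 1 (median 0.07), DMSO replicate 2 (0.10) or 4OHT replicate 3 (0.17). In both replicate 3 libraries 15 of the 16 targets were lower than the mean of replicates 1 and 2 of the same group.

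Msi1, a stem cell RNA-binding protein gene, fell from 46.7 ± 9.1 to 19.6 ± 4.25 CPM (log2 fold change -1.26, adjusted p = 0.0455), the 1 called gene among 15 tested stem cell markers. Without the replicate block the list did not move (camera adjusted p = 0.143, median -0.18). With replicate number as a block, it fell (camera adjusted p = 0.0364, adjusted p = 0.731 with an estimated correlation), with Prom1 (0.28, adjusted p = 0.0365) and Aqp4 (0.54, 0.00709) higher and Msi1 and Igfbp4 (-0.29, 0.0224, chosen after its values were seen) lower. Rgmb was at 72.1 and 54.9 CPM (adjusted p = 0.187). When adjusted over the list alone 2 were higher and 2 lower (2 and 5 with the block). The list passed without DMSO replicate 3 (0.0246, median -0.29), 4OHT replicate 1 (0.0395, median -0.27) or 4OHT replicate 2 (0.0482, median -0.37), and the median was -0.09 without DMSO replicate 2 and -0.04 without 4OHT replicate 3. It did not pass without replicate 3 of both groups (0.0735, and 0.171 with the block). Stem cell markers were lower in both replicate 3 libraries, with medians of -0.44 and -0.51. Msi1 lost its call without DMSO replicate 1 (0.111) or 2 (0.164), without 4OHT replicate 1 (0.136), 2 (0.136) or 3 (0.122), with library totals alone (0.0501) and with the filter at 10 CPM (0.0655).

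Genes of the cell cycle did not pass over all genes, singly or as a list. Of 22 tested proliferation genes 0 were called by edgeR, DESeq2 or limma-voom, 0 at an unadjusted p under 0.05 (1 higher and 2 lower with the block) and 0 when adjusted over the list alone, with a median of 0 and a camera adjusted p of 0.861. Cdc20 was at 160 ± 9.05 and 176 ± 7.84 CPM (adjusted p = 0.372), Birc5 at 80.0 and 73.5 CPM (0.382), Pcna at 254 and 236 CPM (0.532) and Tyms at 64.9 and 61.0 CPM (0.663). In both replicate 3 libraries 21 of the 22 genes were lower than in replicates 1 and 2.

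Enterocyte genes of the brush border and nutrient transport fell as a group after 4OHT in the preset test. In that test most other splits of the libraries moved at least as many lists as the real one. All 25 tested members had a negative log2 fold change, with a median of -0.64 (camera adjusted p = 1.18e-06, adjusted p = 0.787 with an estimated correlation). Single genes did not pass without the block: edgeR and limma-voom called 0, DESeq2 called 4 lower, 10 were lower at an unadjusted p under 0.05 (21 lower with the block), and 0 passed when adjusted over the list alone. With the replicate block 11 fell, and 21 did so when adjusted over the list alone. These included the peptide transporter gene Slc15a1, from 21.4 ± 2.08 to 13.3 ± 3.0 CPM (-0.71, adjusted p = 0.0184), Mep1b, from 172 to 116 CPM (-0.59, adjusted p = 0.0212), and Cdhr2, from 335 to 258 CPM (-0.38, adjusted p = 0.0249). The lactase gene Lct was at 14.1 ± 5.69 and 6.28 ± 1.93 CPM (-1.16, adjusted p = 0.156, and 0.0994 with the block). In both replicate 3 libraries 22 of the 25 genes were higher than in replicates 1 and 2, and the median was -0.27 without DMSO replicate 3 (camera adjusted p = 0.000826).

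Genes for lipid absorption and lipoprotein assembly fell as a group (19 tested, median -0.48, camera adjusted p = 0.0165, adjusted p = 0.792 with an estimated correlation). No member passed without the block: edgeR and limma-voom called 0, DESeq2 called 2 lower, 1 was higher and 3 lower at an unadjusted p under 0.05 (3 higher and 13 lower with the block), and 1 was lower when adjusted over the list alone (3 higher and 13 lower with the block). In the fit with the replicate block 6 fell and 1 rose. The apolipoprotein genes Apoc2 (46.9 ± 5.31 to 27.7 ± 5.06 CPM, -0.77, adjusted p = 0.00659), Apoa1 (719 to 423 CPM, -0.76, 0.00581) and Apob (874 to 640 CPM, -0.44, 0.0143) fell and the acyltransferase gene Dgat2 (95.5 to 125 CPM, 0.38, 0.0179) rose. The list call was lost without DMSO replicate 3 (0.378, median -0.08) and without 4OHT replicate 2 (0.224, median -0.33). In both replicate 3 libraries 17 of the 19 genes were higher than in replicates 1 and 2.

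Xenobiotic metabolism genes also fell as a group (26 tested, 24 with a negative log2 fold change, median -0.40, camera adjusted p = 0.0123, adjusted p = 0.792 with an estimated correlation). Without the block edgeR, DESeq2 and limma-voom called 0 members, 1 was higher and 3 lower at an unadjusted p under 0.05 (1 higher and 21 lower with the block), and 0 passed when adjusted over the list alone (1 higher and 21 lower with the block). When the replicate block was included, 11 fell and 1 rose. The nuclear receptor genes Nr1i2 (68.3 ± 10.9 to 51.0 ± 5.98 CPM, -0.42, adjusted p = 0.0135) and Nr1i3 (33.0 to 19.2 CPM, -0.72, 0.0336) and the sulfotransferase gene Sult1b1 (79.8 to 50.9 CPM, -0.65, 0.00581) fell, and Gsta4 (489 to 755 CPM, 0.58, 0.0366) rose. The list call was lost without DMSO replicate 3 (0.493, where the median was 0.06 and the test still pointed down), 4OHT replicate 1 (0.0549) or 4OHT replicate 2 (0.404, median -0.19), and the median was -0.70 without 4OHT replicate 3. In both replicate 3 libraries 25 of the 26 genes were higher than in replicates 1 and 2.

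Nuclear-encoded oxidative phosphorylation genes fell slightly as a group (21 tested, all negative, median -0.16, camera adjusted p = 1.55e-05, adjusted p = 0.787 with an estimated correlation). Of these edgeR, DESeq2 and limma-voom called 0, 6 were lower at an unadjusted p under 0.05 (16 lower with the block) and 0 passed when adjusted over the list alone; with the replicate block 0 passed over all genes and 15 were lower when adjusted over the list alone. Sdhb was at 127 and 105 CPM (adjusted p = 0.314), Ndufv1 at 252 and 226 CPM (0.329) and Cox6c at 211 and 182 CPM (0.329). The median was -0.10 without DMSO replicate 3, and 20 of the 21 genes were higher in both replicate 3 libraries than in replicates 1 and 2.

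Fatty acid oxidation genes did not move as a list (15 tested, median -0.10, camera adjusted p = 0.164), except without DMSO replicate 2 (0.0123, median -0.21) or 4OHT replicate 3 (0.0249). Without DMSO replicate 3 the test pointed up (0.686, median 0.04), and the median was -0.16 without DMSO replicate 1 and -0.04 without 4OHT replicate 2. Of the 15 genes edgeR, DESeq2 and limma-voom called 0, 1 was lower at an unadjusted p under 0.05 (5 lower with the block), and 0 passed when adjusted over the list alone (3 lower with the block). Under the replicate block Ehhadh, a peroxisomal enzyme gene, fell from 66.1 to 44.0 CPM (-0.55, adjusted p = 0.0415). Acaa1b (28.7 and 14.9 CPM, adjusted p = 0.415), Etfdh (90.8 and 78.4 CPM, 0.456) and Acadm (94.8 and 82.6 CPM, 0.593) did not pass. The list was higher in replicate 3 of both groups than in replicates 1 and 2 for 14 of its 15 genes.

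Intestinal transcription factor genes did not move together (19 tested, median -0.10, camera adjusted p = 0.89), and the test pointed up without DMSO replicate 3 (0.336, median 0.09) or 4OHT replicate 2 (0.788, median -0.06). The median was also -0.06 without 4OHT replicate 1. By edgeR and limma-voom 0 were called, DESeq2 called 1 higher and 1 lower, 2 were higher and 1 lower at an unadjusted p under 0.05 (4 higher and 4 lower with the block), and 1 was higher when adjusted over the list alone (4 higher and 4 lower with the block). With replicate number as a block, Foxa1, a pioneer factor gene, rose from 84.7 ± 12.7 to 124 ± 8.47 CPM (0.56, adjusted p = 0.0143) and Maf fell from 9.49 to 5.66 CPM (-0.74, 0.0214). Without DMSO replicate 3 Foxa1 passed without the block (0.43, 0.0386). Elf3 was at 414 and 476 CPM (0.308) and Klf4 at 28 and 34.1 CPM (0.343).

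Bile acid and ileal genes went both ways (7 tested, median -0.42, camera adjusted p = 0.72), and without DMSO replicate 3 the median was -0.14 and the test pointed up (0.739). By edgeR, DESeq2 and limma-voom 0 were called, 1 was higher and 1 lower at an unadjusted p under 0.05 (3 higher and 4 lower with the block), and 0 passed when adjusted over the list alone (3 higher and 4 lower with the block). With the replicate block the guanylin gene Guca2a rose from 73.2 to 89.1 CPM (0.29, adjusted p = 0.0446), while Guca2b, for uroguanylin, fell from 63.6 to 45.4 CPM (-0.49, 0.013) and Slc51b fell from 2.58 to 1.19 CPM (-1.14, 0.0414). The bile acid transporter gene Slc10a2 was at 3.99 and 6.49 CPM (adjusted p = 0.267). In replicate 3 of both groups 6 of the 7 genes were higher than in replicates 1 and 2.

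Goblet cell markers rose as a group after 4OHT (14 tested, 13 with a positive log2 fold change, median 0.57, camera adjusted p = 0.00467, adjusted p = 0.787 with an estimated correlation). Bcas1 was the 1 called gene, from 16.9 ± 3.89 to 43.8 ± 10.4 CPM (log2 fold change 1.38, SE 0.219, adjusted p = 0.0455), and 3 were higher when adjusted over the list alone (8 higher and 1 lower with the block). In the fit with the replicate block 8 rose and 1 fell. Clca1, from 211 ± 66.3 to 535 ± 220 CPM (1.31, adjusted p = 0.00581), and Zg16, from 128 to 401 CPM (1.65, 0.00192), both secreted goblet cell products, rose, and the chemokine gene Ccl9 fell from 52.2 to 31.5 CPM (-0.69, 0.021). The median was 1.07 without DMSO replicate 3, where Clca1 (1.62, 0.0497) and Zg16 (2.08, 0.0412) passed without the block. The list call was lost without DMSO replicate 1 (0.0802) or 2 (0.0582). Bcas1 lost its call without DMSO replicate 1 (0.12) or 2 (0.169), without 4OHT replicate 1 (0.197), 2 (0.0653) or 3 (0.14), with the filter at 10 CPM (0.0651) and with limma-voom (0.0512). In both replicate 3 libraries 13 of the 14 markers were higher than in replicates 1 and 2.

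Enteroendocrine markers did not move as a list (15 tested, median 0.28, camera adjusted p = 0.164), except without DMSO replicate 3 (0.00551) or 4OHT replicate 2 (0.00535). The median was 0.18 without DMSO replicate 1, 0.16 without DMSO replicate 2 and 0.18 without 4OHT replicate 3. The 3 tools edgeR, DESeq2 and limma-voom called 0, 2 were higher at an unadjusted p under 0.05 (7 higher with the block), and 0 passed when adjusted over the list alone (7 higher with the block). When the replicate block was included, Chga, the chromogranin A gene, rose from 40.9 to 54.2 CPM (0.40, adjusted p = 0.0478). Pyy (1.28 and 1.94 CPM, adjusted p = 0.281), Gcg (3.68 and 5.16 CPM, 0.281) and Sst (1.20 and 2.29 CPM, 0.379, and 0.0482 without DMSO replicate 3) are hormone genes at low levels. Both replicate 3 libraries had higher enteroendocrine markers, with medians of 0.41 and 0.27.

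Tuft cell markers were at low levels and did not move as a list (9 tested, median 0.18, camera adjusted p = 0.197), except without DMSO replicate 3 (0.00363, median 0.43) or without replicate 3 of both groups (0.0145, and 0.0268 with the block, median 0.39). The median was 0.03 without DMSO replicate 1, 0.11 without DMSO replicate 2, 0.07 without 4OHT replicate 1 and 0.11 without 4OHT replicate 3. By edgeR and limma-voom 0 were called, DESeq2 called 1 higher, 2 were higher at an unadjusted p under 0.05 (1 higher with the block), and 1 was higher when adjusted over the list alone. Under the replicate block Avil rose from 2.47 to 4.19 CPM (0.76, adjusted p = 0.0435). Alox5ap (0.371 and 0.618 CPM, adjusted p = 0.273), Sh2d6 (1.41 and 1.05 CPM, 0.454) and Rgs13 (0.957 and 1.40 CPM, 0.509) did not pass.

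Regulators of the secretory lineage did not pass over all genes, singly or as a list (10 tested, median -0.02, camera adjusted p = 0.861). By edgeR, DESeq2 and limma-voom 0 were called, 0 at an unadjusted p under 0.05 (2 higher and 3 lower with the block) and 0 when adjusted over the list alone. Creb3l4 was at 8.61 and 10.8 CPM (adjusted p = 0.38), Bhlha15 at 24.2 and 20.4 CPM (0.384), Neurog3 at 9.87 and 8.04 CPM (0.41) and Spdef at 21.2 and 26.6 CPM (0.496). Genes of the Notch pathway did not move either (10 tested, median -0.05, camera adjusted p = 0.406). Among them edgeR, DESeq2 and limma-voom called 0, 1 was lower at an unadjusted p under 0.05 (3 higher and 2 lower with the block) and 0 passed when adjusted over the list alone (2 higher and 2 lower with the block). With replicate number as a block, Notch2 rose from 34.1 to 42.9 CPM (0.35, adjusted p = 0.0446), and Jag2 (40.4 and 53.3 CPM, 0.07) and Lfng (24.7 and 19.1 CPM, 0.0763) did not pass in that fit.

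Genes of gastric epithelium rose as a group (7 tested, 3 higher, median 2.13, camera adjusted p = 0.000866, adjusted p = 0.746 with an estimated correlation, and 0.04 by fry without and 0.183 with the block). Without its top member the median was 1.36 (camera adjusted p = 0.0165). Tff1 is given above. Gkn1 rose from 0.401 ± 0.159 to 1.79 ± 0.271 CPM (log2 fold change 2.13, SE 0.294, adjusted p = 0.0326) and Gkn2 from 0.084 to 0.766 CPM (3.10, 0.0362), both products of gastric surface mucous cells, and both stayed at low levels. When adjusted over the list alone 4 were higher and 1 lower. With the replicate block Tff2 also rose (0.138 to 0.851 CPM, 2.58, 0.0143, chosen after its values were seen) and Pgc, the pepsinogen C gene, fell (1.47 to 0.515 CPM, -1.53, 0.0249). Without DMSO replicate 1 the adjusted p was 0.0576 for Gkn1, 0.107 for Gkn2 and 0.0572 for Tff1. Without DMSO replicate 2 it was 0.15, 0.107 and 0.0606, and without 4OHT replicate 1 it was 0.144, 0.162 and 0.059. Gkn1 and Gkn2 were at 0.101 and 0.0745 without 4OHT replicate 2 and at 0.104 and 0.132 without 4OHT replicate 3, where Tff1 kept its call.

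Genes of fetal-like and regenerative epithelium rose as a group (14 tested, all positive, median 0.70, camera adjusted p = 5.77e-05, adjusted p = 0.787 with an estimated correlation). Single members did not pass without the block: edgeR and limma-voom called 0, DESeq2 called 3 higher, 7 were higher at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. In the fit with the replicate block 2 rose, among them Ly6a, which encodes Sca-1, from 175 to 356 CPM (1.10, adjusted p = 0.0342), and 10 were higher when adjusted over the list alone. Il1rn was at 106 and 201 CPM (0.145, and 0.0475 without DMSO replicate 3) and Msln at 440 and 834 CPM (0.212, and 0.0441 without DMSO replicate 3). DMSO replicate 3 held less of these transcripts than DMSO replicates 1 and 2, with a median of -1.17, beside -0.12 for 4OHT replicate 3. The list median was 0.40 without DMSO replicate 3 (camera adjusted p = 0.000238).

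Genes of the p53 response rose slightly as a group (16 tested, median 0.21, camera adjusted p = 0.00158, adjusted p = 0.787 with an estimated correlation). By edgeR and limma-voom 0 were called, DESeq2 called 3 higher, 7 were higher at an unadjusted p under 0.05, and 5 were higher when adjusted over the list alone (9 with the block). When the replicate block was included, 5 rose, among them the cyclin gene Ccng1 (207 ± 11 to 284 ± 21.1 CPM, 0.46, adjusted p = 0.0216), Phlda3 (24.3 to 39.3 CPM, 0.72, 0.0329), Zmat3 (62.4 to 80.2 CPM, 0.37, 0.0434) and Trp53inp1 (38.8 to 52.5 CPM, 0.43, 0.046). Without DMSO replicate 3, Ccng1 (0.0444) and Phlda3 (0.0419) passed without the block. Immediate early genes rose as a group as well (10 tested, median 0.53, camera adjusted p = 0.0123, adjusted p = 0.746 with an estimated correlation). Among these edgeR and limma-voom called 0, DESeq2 called 2 higher, 3 were higher at an unadjusted p under 0.05 (5 higher with the block) and 2 when adjusted over the list alone (3 with the block). The phosphatase gene Dusp1 was at 2.93 and 4.42 CPM (adjusted p = 0.15), Ier3 at 17.0 and 29.0 CPM (0.15, and 0.0497 without DMSO replicate 3), Junb at 86.7 and 113 CPM (0.225) and Fosl1 at 7.60 and 11.8 CPM (0.373). Their median was 0.31 without 4OHT replicate 3, and 0.23 without replicate 3 of both groups (0.22 with the block).

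**Figure D3:**
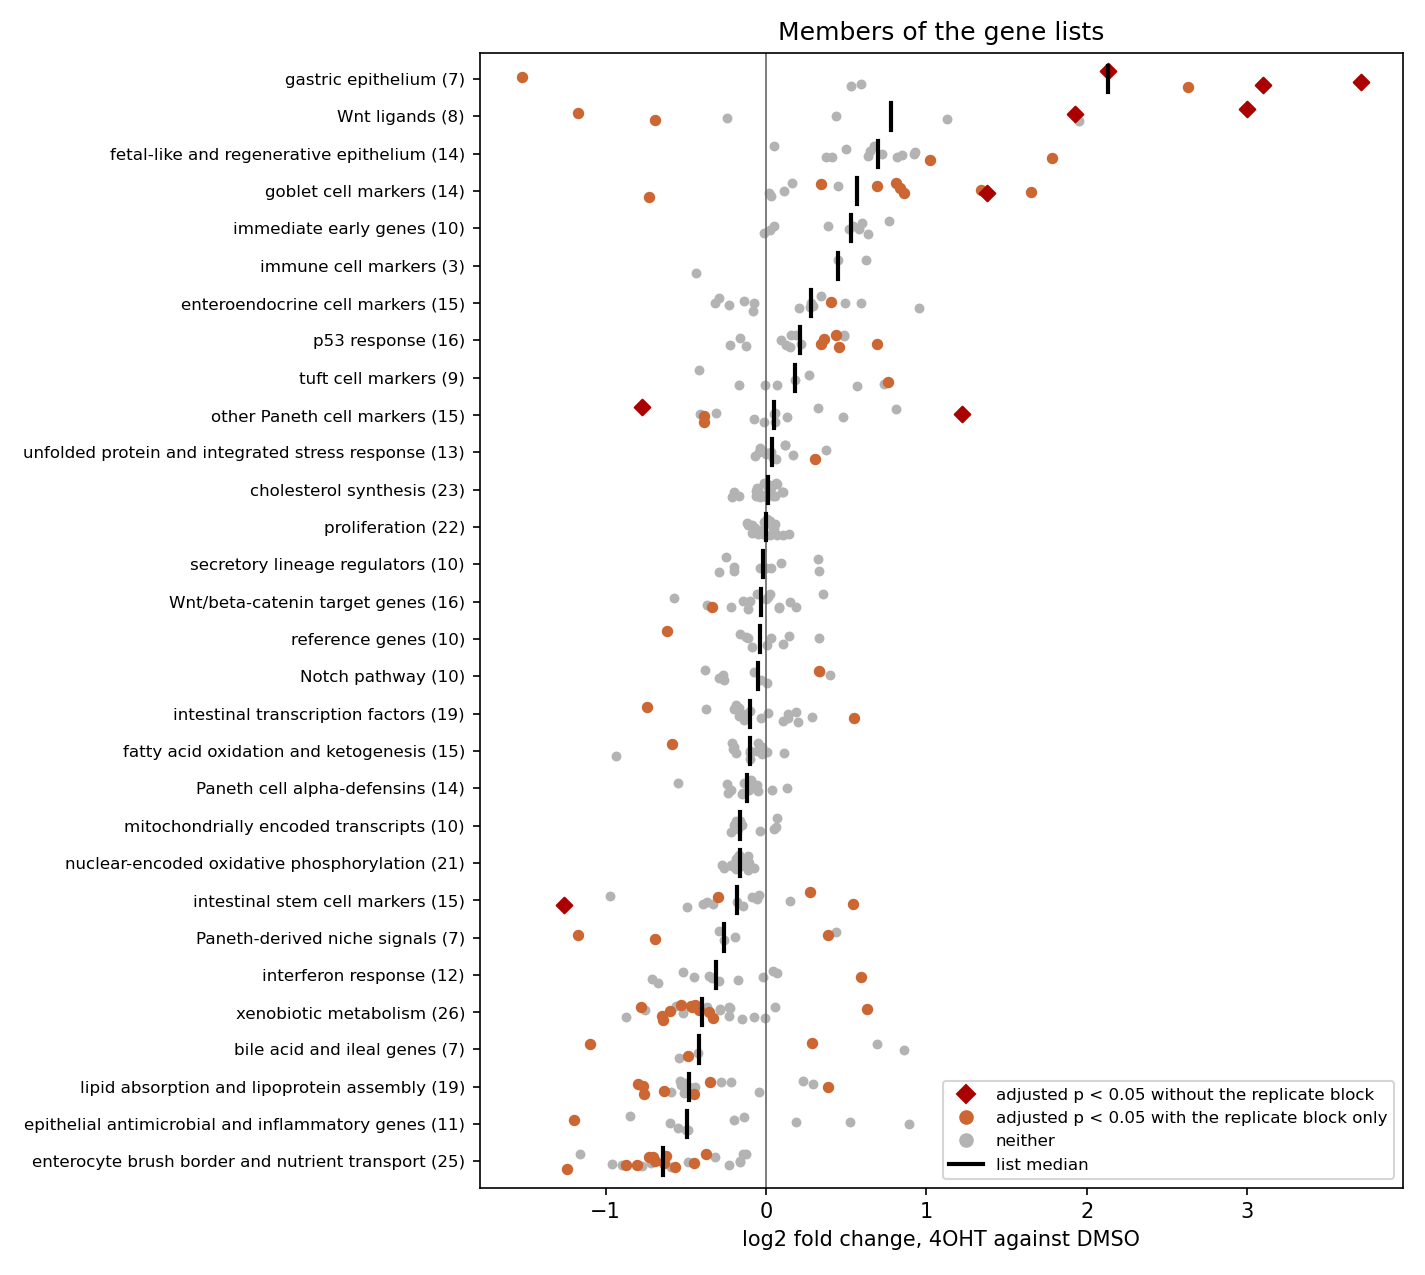
Log2 fold change (4OHT against DMSO, horizontal axis) of each tested member of 30 gene lists, 1 line per list with the number tested in brackets and a black bar at the list median. Red diamonds are genes past an adjusted p of 0.05 without the replicate block, orange points pass only with the block and grey points pass in neither; all 25 enterocyte genes lie to the left of 0 and 13 of 14 goblet cell genes to the right.

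Interferon response genes did not move as a list (12 tested, median -0.31, camera adjusted p = 0.176), except without DMSO replicate 3 (0.047), without its top member (0.0448) or with the block without replicate 3 of both groups (0.0268), and the median was -0.13 without DMSO replicate 1 and -0.19 without 4OHT replicate 2. By edgeR and limma-voom 0 were called, DESeq2 called 1 higher, 1 was higher and 1 lower at an unadjusted p under 0.05 (1 higher and 4 lower with the block), and 1 was higher when adjusted over the list alone. Under the replicate block Oas1a rose from 6.91 to 10.4 CPM (0.59, adjusted p = 0.0287), and it passed without the block when DMSO replicate 3 was left out (0.0386). Irf7 (9.82 and 7.75 CPM, 0.281) and Oasl2 (2.01 and 1.41 CPM, 0.346) did not pass. Antimicrobial and inflammatory genes gave a camera adjusted p of 0.0905 (11 tested, median -0.49), which passed without 4OHT replicate 3 (0.00947, median -0.37) and without replicate 3 of both groups (0.0159, and 0.00458 with the block, median -0.43). The median was -0.23, -0.31 and -0.30 without DMSO replicates 1, 2 and 3 and -0.24 and -0.19 without 4OHT replicates 1 and 2. Of these edgeR and limma-voom called 0, DESeq2 called 1 lower, 2 were lower at an unadjusted p under 0.05 (2 higher and 4 lower with the block) and 1 when adjusted over the list alone (2 higher and 3 lower with the block). With replicate number as a block, Nos2, the inducible nitric oxide synthase gene, fell from 5.23 to 2.28 CPM (-1.22, 0.0341). Pigr, the polymeric immunoglobulin receptor gene, was at 1549 and 1024 CPM (0.273), Ccl20 at 6.10 and 4.16 CPM (0.346) and Reg3b at 39.6 and 28 CPM (0.404).

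Genes of the unfolded protein and integrated stress response did not move as a list (13 tested, median 0.04, camera adjusted p = 0.295). Only without DMSO replicate 3 did the list pass (0.0223, median 0.15). The median was -0.01 and 0.01 without DMSO replicates 1 and 2. It was 0.07, 0.08 and 0 without 4OHT replicates 1, 2 and 3. The 3 tools edgeR, DESeq2 and limma-voom called 0, 1 was higher at an unadjusted p under 0.05 (2 higher with the block) and 0 passed when adjusted over the list alone (1 higher with the block). With the replicate block the asparagine synthetase gene Asns rose from 168 to 208 CPM (0.30, adjusted p = 0.0253). Creld2 (76.2 and 82.5 CPM, 0.471), Chac1 (3.65 and 4.74 CPM, 0.481) and Hspa5 (807 and 876 CPM, 0.606) did not pass. Cholesterol synthesis genes did not differ (23 tested, median 0.01, mean -0.01 with the test pointing down, camera adjusted p = 0.951). There edgeR, DESeq2 and limma-voom called 0, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone, with Dhcr7 at 124 and 108 CPM (0.418), Srebf2 at 598 and 645 CPM (0.451) and Hmgcs1 at 538 and 576 CPM (0.546).

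Tested list markers of cell types outside the epithelium lay between 0.259 and 5.52 CPM. Immune markers had 3 tested members (camera adjusted p = 0.373, median 0.45, and 0.19 without 4OHT replicate 2). By edgeR and limma-voom 0 were called, DESeq2 called 1 higher, and 1 was higher at an unadjusted p under 0.05 and when adjusted over the list alone: Cd68 (2.70 and 4.18 CPM, adjusted p = 0.15). Itgam was at 1.92 and 1.41 CPM (0.593) and Csf1r at 0.259 and 0.36 CPM (0.654). Mesenchymal markers had 2 tested members, Pdgfrb (1.08 and 1.15 CPM, 0.933) and Vim (5.43 and 5.52 CPM, 0.971), and endothelial markers 2, Tek (0.436 and 0.519 CPM, 0.762) and Pecam1 (0.339 and 0.396 CPM, 0.767). In both lists edgeR, DESeq2 and limma-voom called 0 members, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Both were too short to test as sets, except that mesenchymal markers reached 3 tested members in 4 fits without 1 library and in the fits without replicate 3 of both groups (0.0507, and 0.0528 with the block). They passed without DMSO replicate 3 (0.0385, median 0.52), but not without DMSO replicate 1 (0.622, -0.07), DMSO replicate 2 (0.596, -0.11) or 4OHT replicate 3 (0.716, -0.08). Of genes outside the lists, chosen after their values were seen, the mast cell protease genes Mcpt1 (0.582 to 5.68 CPM, log2 fold change 3.23, adjusted p = 0.0132, and 0.0694 without the block) and Mcpt2 (7.01 to 28 CPM, 2.03, 0.0458, and 0.165) rose with the replicate block, and both were higher after 4OHT in all 3 pairs.

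Mitochondrially encoded transcripts gave a camera adjusted p of 0.0867 (10 tested, median -0.16), which passed without DMSO replicate 3 (0.0385), 4OHT replicate 2 (0.0438) or 4OHT replicate 3 (0.0172), with the filter at 10 CPM (0.0265) and without replicate 3 of both groups (0.0174, and 0.0269 with the block), and the median was -0.06 without DMSO replicate 1. By edgeR, DESeq2 and limma-voom 0 were called, 1 was lower at an unadjusted p under 0.05 (0 with the block) and 0 passed when adjusted over the list alone. mt-Nd2 was at 1530 ± 126 and 1314 ± 89.0 CPM (adjusted p = 0.316), mt-Nd5 at 1680 and 1463 CPM (0.428), mt-Nd4 at 912 and 803 CPM (0.438) and mt-Nd1 at 3324 and 2948 CPM (0.489). Of genes chosen after their values were seen, mt-Co2 and mt-Co3 had 4.2 and 3.74 CPM in DMSO beside 8898 CPM for mt-Co1, so their counts cannot be read as levels. Both were among the 10 tested members, so the list test without the 10 CPM filter rests in part on such counts. With that filter 7 members were tested. Reference genes did not move as a list (10 tested, median -0.04, camera adjusted p = 0.439). Of these edgeR and limma-voom called 0, DESeq2 called 1 lower, 1 was higher and 1 lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. In the fit with the replicate block B2m, the beta-2-microglobulin gene, fell from 157 ± 25 to 102 ± 7.91 CPM (-0.61, adjusted p = 0.011), and it passed without the block when DMSO replicate 3 was left out (-0.48, 0.0295). Actb was at 3365 and 4240 CPM (0.228) and Sdha at 495 and 442 CPM (0.408).

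The authors' deposited comparison, set beside these values, held 674 genes with an edgeR adjusted p under 0.05 (447 higher, 227 lower) and 300 with a DESeq adjusted p under 0.05 (239 higher, 61 lower), and all 300 were among the 674. Of the 132 genes called here without the block, 130 were in the deposited edgeR set and 116 in the deposited DESeq set, and 512 of the 674 were called here with the block. The deposited values for Wnt3 were a log2 fold change of -0.69 with adjusted p of 0.029 (edgeR) and 0.07 (DESeq), and for Lyz1 -0.78 with 5.7e-07 and 1.4e-05. For Hnf4a they were -1.01 with 2.1e-12 and 4e-07.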

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

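The alternatives without replicate 3 of both groups, DESeq2 with the replicate block, and the replicate block with an estimated correlation were chosen after seeing the data. The counts without the block (132 genes, 102 higher and 30 lower) moved by more than 1.5 times in the settings that follow, and the cause was not tested unless it is given. The replicate block gave 1017 (580 and 437), DESeq2 735 (474 and 261), DESeq2 with the replicate block 1259 (683 and 576), and the replicate block without replicate 3 of both groups 2678 (1482 and 1196). This last fit had very few residual degrees of freedom, so its count does not show how many genes truly changed. Stricter criteria gave fewer by construction, with 68 (54 and 14) at an absolute log2 fold change of at least 1 and 17 (13 and 4) at an adjusted p under 0.01. With at least 10 CPM in 3 libraries, where fewer genes were tested, 56 were called (38 and 18). Leaving out 1 library gave 4 to 340 (3 to 253 higher, 1 to 87 lower), with 6, 4 and 340 without DMSO replicates 1, 2 and 3 and 9, 20 and 12 without 4OHT replicates 1, 2 and 3. Of the 132 genes, 6, 4, 130, 9, 20 and 12 kept their call in that order. Within 1.5 times were size factors by the DESeq2 method (130), library totals alone (138), no filter (137) and limma-voom (123).

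Of the 30 lists, 9 passed with the preset correlation. With a correlation estimated within each list 0 passed (adjusted p from 0.746 to 0.982, 2 at an unadjusted p under 0.05), and 0 with the replicate block and an estimated correlation (0 at an unadjusted p under 0.05). By fry 1 passed, gastric epithelium (adjusted p = 0.04), and with the block fry passed 0 lists (lowest adjusted p 0.183, gastric epithelium among others). At the preset correlation 10 passed with the replicate block (the same 9 and the stem cell markers), 9 with at least 10 CPM in 3 libraries, 10 without the top member of each list, 13 with the replicate block without replicate 3 of both groups and 12 without replicate 3 and without the block. Leaving out 1 library gave 9 to 15. The cause of the lost list calls was not tested. The medians without and with the block were 0.57 and 0.65 for goblet cell markers, -0.64 and -0.62 for enterocyte genes, -0.48 and -0.41 for lipid absorption, -0.40 and -0.41 for xenobiotic metabolism, 0.70 and 0.80 for fetal-like epithelium, 0.21 and 0.21 for the p53 response, -0.16 and -0.16 for oxidative phosphorylation, 2.13 and 2.16 for gastric epithelium, and 0.53 and 0.49 for immediate early genes. Over the fits without 1 library the median ran from 0.38 to 1.07 for goblet cell markers, from -0.65 to -0.08 for lipid absorption and from -0.70 to 0.06 for xenobiotic metabolism. Without replicate 3 of both groups and without the block it was 0.92 for goblet cell markers, -0.29 for lipid absorption, 0.42 for fetal-like epithelium and 0.23 for immediate early genes, and without the top member it was 1.36 for gastric epithelium. The goblet list was lost without DMSO replicate 1 (adjusted p = 0.0802) or 2 (0.0582). Lipid absorption was lost without DMSO replicate 3 (0.378) or 4OHT replicate 2 (0.224), and xenobiotic metabolism without DMSO replicate 3 (0.493), 4OHT replicate 1 (0.0549) or 4OHT replicate 2 (0.404). The gastric list has no value with at least 10 CPM in 3 libraries, since too few members were left.

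Of 138 genes that met the naming rule, 26 were called, and 0 of these reversed in the alternatives that tested them. Of the 26, 19 kept their call with the replicate block, DESeq2, limma-voom, the 2 other scalings and the 2 other filters where these tested them, while 5 lost it with at least 10 CPM in 3 libraries, 1 with library totals alone and 4 with limma-voom. Without DMSO replicates 1, 2 and 3, 22, 24 and 0 lost it, and without 4OHT replicates 1, 2 and 3, 21, 16 and 21 did. The replicate block added 41 calls among the 138, DESeq2 29 and leaving out DMSO replicate 3 12. Hnf4g, not called in any fit, reversed to 0.36 without DMSO replicate 3 (adjusted p = 0.503), and over the fits without 1 library it ran from -0.42 to 0.36 (adjusted p from 0.503 to 0.984). The cause was not tested. The median log2 fold change of all tested genes was -0.004 and lay between -0.012 and 0.001 in the alternatives. Genes with fewer than 10 counts over the 6 libraries were not in the table, and Gkn2, at 0.084 CPM in DMSO, was near the detection limit.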

Other observations

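Among the tests in this part, those of gastric pit cells, sequencing depth and culture maturity were chosen only after the result was seen, as were the genes and the 2 gene lists named here that the report does not name. The names of the explanations for the squamous and gastric genes were narrowed to those genes after the results were known.

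A list of 26 squamous and urothelial genes, written after the called genes had been seen, had 18 tested members, of which 5 rose after 4OHT and 0 fell (8 and 0 with the replicate block), with a median log2 fold change of 1.12. Besides Krt4 and Ivl, these were Dmkn, which encodes the epidermal protein dermokine (0.854 ± 0.118 to 6.32 ± 1.48 CPM, 2.88, adjusted p = 0.00816), the keratin gene Krt78 (0.919 to 2.72 CPM, 1.56, adjusted p = 0.0264) and the uroplakin gene Upk1b (6.73 to 15.2 CPM, 1.17, adjusted p = 0.0205). Without DMSO replicate 1, DMSO replicate 2 and 4OHT replicate 1 in turn, the adjusted p was 0.0572, 0.0606 and 0.059 for Dmkn, 0.0804, 0.11 and 0.132 for Krt78, 0.0756, 0.107 and 0.0768 for Upk1b, 0.0674, 0.0868 and 0.0645 for Krt4 and 0.0804, 0.161 and 0.155 for Ivl. Without 4OHT replicate 2 and 4OHT replicate 3 it was 0.0774 and 0.104 for Krt78, 0.0704 and 0.0621 for Upk1b, and 0.0766 and 0.0988 for Krt4, and without 4OHT replicate 3 it was 0.124 for Ivl. A second such list, of 13 gastric genes, had 8 tested members with 3 higher and 0 lower (4 and 1 with the block) and shares its called genes with the gastric list of the report.

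Eya2, a transcriptional coactivator and phosphatase gene, rose from 0.253 ± 0.0358 to 4.20 ± 0.678 CPM (SD, n = 3, log2 fold change 4.04, edgeR adjusted p = 0.00291) and kept its call without each library in turn (0.00292 to 0.0315). Gsdmc2, a gasdermin gene with near-identical neighbours, rose from 0.145 to 3.92 CPM (4.73, adjusted p = 0.00816). Its call was lost without DMSO replicate 1 (5.01, 0.0572), DMSO replicate 2 (4.55, 0.0606) or 4OHT replicate 1 (4.62, 0.059), with a fold change of similar size. The fucosyltransferase gene Fut1, on chromosome 7 like Fut2, rose from 4.29 to 8.01 CPM (0.90, adjusted p = 0.0326). Without DMSO replicate 1 or 2 its adjusted p was 0.102 and 0.117, and without 4OHT replicate 1, 2 or 3 it was 0.132, 0.105 and 0.122. In the blocked fit only, the metallothionein genes Mt1 (341 to 175 CPM, -0.86, adjusted p = 0.0448) and Mt2 (244 to 97.0 CPM, -1.22, 0.0272), the chemokine gene Ccl25 (171 to 95.9 CPM, -0.80, 0.0123) and the claudin gene Cldn15 (231 to 110 CPM, -1.03, 0.00863) fell. All 4 were highest in DMSO replicate 3, and without that library and without the block their log2 fold changes were -0.48, -0.76, -0.47 and -0.64 (adjusted p = 0.0699, 0.0796, 0.287 and 0.207), beside -0.96, -1.33, -0.83 and -1.07 with all libraries. Features known to gather ribosomal RNA reads were lower as well with the block, with Gm23935 at 150 ± 93.4 and 41.9 ± 5.06 CPM (-1.68, 0.0405), Mir6236 at 39.1 and 8.81 CPM (-2.03, 0.0206) and Lars2 at 225 and 97.7 CPM (-1.12, 0.0465). Each of these 3 was highest in DMSO replicate 3, and without that library they passed without the block (0.00543, 0.00543 and 0.0169, with log2 fold changes of -1.21, -1.58 and -0.78).

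Some squamous and gastric genes were higher in the 4OHT libraries, while others of the same lists, such as Krt15 (-0.14), Dsg3 (-0.43), Pkp1 (-0.19), Upk3a (-0.47), Pgc (-1.52) and Gkn3 (-0.04), were not, and the squamous list was not tested as a set. Squamous cells in the cultures would bring the keratins Krt5 (0.884 and 1.34 CPM), Krt13 (0.102 and 0.506 CPM) and Krt14 (0.893 and 1.91 CPM). Their summed rise was at most 1.35% of the rise of Krt4 in any pair (1.05%, 0.808% and 1.35%). This argues against such cells as the source of the Krt4 rise. Krt13 itself rose with the replicate block (2.33, edgeR adjusted p = 0.0404, and 0.0797 without the block). The test did not cover squamous genes at lower levels, such as Ivl, Dmkn and Krt78, so squamous cells stay open for these. Gastric pit cells would bring Gkn1 (0.401 and 1.79 CPM) and Gkn2 (0.084 and 0.766 CPM). Their summed rise was at most 3.39% of that of Tff1, from 9.8 to 128 CPM (1.61%, 3.39% and 1.24%). This argues against pit cells as the source of the Tff1 rise. The test did not cover the rises of Gkn1, Gkn2 and other gastric genes at low levels, so pit cells stay open for these. A change within the organoid epithelium after 4OHT may underlie the rises of Krt4 and Tff1, as a hypothesis found on the same data and not itself tested. No library received 4OHT without floxed alleles, so loss of Hnf4a and exposure to 4OHT or Cre activity were not separated by the design.

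Replicate 3 of both groups stood apart from replicates 1 and 2 in differentiation genes. Its deviations in the 2 groups correlated at 0.43 across genes. This is the same value that served to pair the libraries by number, so it was known before the depth test was chosen. DMSO replicate 3 was the shallowest and 4OHT replicate 3 the deepest library, so depth would move them opposite ways. The positive correlation argues against depth. Spearman's rho between deviation and transcript length was -0.08 in DMSO and -0.17 after 4OHT (bootstrap SE 0.009) across 14487 genes. Degradation as the cause in both groups was to give a rho under -0.2 in both, and the DMSO value argues against that, though by little: it lies just over the bound of -0.1, its margin of 2 SE was added after the value was seen, and the 4OHT value lies between the bounds, so a part played by degradation after 4OHT stays open. A difference between culture or harvest rounds could also give such a shift and stays open, since the labels give no dates, and no biological explanation was tested.

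Enterocyte genes were lower and goblet cell genes higher in the 4OHT libraries. In replicate 3 both lists were higher together. With the replicate block their medians after 4OHT lay 1.27 apart (0.65 for goblet cell genes, 13 of 14 above 0, and -0.62 for enterocyte genes, 25 of 25 below 0). A maturity shift like that of replicate 3 would move both lists the same way, which argues against it as the whole cause. The gap restates the pattern itself, so it is no separate test and leaves a part played by maturity open. Removing the trend with GC content and transcript length kept 89.9% of the goblet median (0.65 to 0.59) and 101% of the enterocyte median (-0.62 to -0.63), which argues against that bias. A shift between the 2 lineages after 4OHT was not tested, list tests with an estimated correlation did not pass (adjusted p = 0.787 for both), and secretory lineage regulators (median -0.02) and Notch pathway genes (-0.05) did not move as lists. Loss of Hnf4a and 4OHT or Cre exposure stay unseparated here as well.

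The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 132 genes and the highest other split 0 (by edgeR, 2181 genes against 103 to 1370 at an unadjusted p under 0.05), so 1 split reached the real count. With the replicate block the real split called 1017 genes and the highest of the other splits that part all 3 pairs 0, so 1 of 4 splits, also too few, reached the real count. For the lists the real split moved 9 and the highest other 14, and 8 of the 10 splits moved at least as many. Among the 4 splits that part all pairs, the block gave 10 lists for the real split and 12 for the highest other, and 2 reached the real number. List calls with the preset correlation were therefore not specific to the real split. The split with 14 lists, DMSO replicates 1 and 2 with 4OHT replicate 2 against the rest put both replicate 3 libraries on the same side, but the split of DMSO replicate 1 with 4OHT replicates 2 and 3 against the rest moved 13 lists and parts all pairs. The other splits that part all pairs, which mix the groups, gave 9, 6 and 13 lists without the block and 7, 6 and 12 with it.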
